A study of Mus musculus with 12 samples.

How the data were processed

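Liver RNA of male mice was measured by RNA sequencing in 12 samples, 1 library per sample. Per the labels' protocols, livers were flash frozen, RNA was taken up in Trizol, and libraries were made from total RNA with a Nugen Ovation kit. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq and DESeq2 1.14.1 were used with the mouse build mm9. The strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes that share reads with near-identical copies or overlapping neighbours are uncertain. The authors deposited whole-number counts per gene symbol for each sample, with no normalization, and the files held no line for unassigned reads. Of the 24062 genes listed, 94.5% had a symbol in the GENCODE annotation of the GRCm38 build given for this work. Because that build differs from the authors' build, no coordinates are given.

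Samples were grouped by the labels into standard diet (SD) controls (n = 3), SD knockouts (n = 3), high-fat diet (HFD) controls (n = 4) and HFD knockouts (n = 2). The labels give each library its own identifier but do not state in words that each came from a separate mouse, so p-values measure the spread between these libraries. Total counts were 2371167 to 3404570 in SD libraries and 7463792 to 10875478 in HFD libraries. The limit that a count of 0 allows was taken as 3 counts over a group, which is 0.360 CPM (counts normalized to library size) in SD controls, 0.358 in SD knockouts, 0.0845 in HFD controls and 0.186 in HFD knockouts. Such limits and intervals cover counting error only.

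Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1), with TMM normalization, a filter on low counts (filterByExpr with its minimum count of 10), 4 group means and 1 estimate of the spread over all 12 libraries. The filter left 12015 genes, and the common biological coefficient of variation was 0.153. The tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over all genes tested, and a gene passed at an adjusted p under 0.05. CPM values use the normalized library sizes and are given as mean ± SD. Standard errors (SE) of log2 fold changes were derived from the test statistic. For a group at 0 in every library the fold is a bound against the limit of 3 counts. Where a group held 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval.

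Gene lists from textbook liver biology, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members, 28 in all, were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists, and again with a correlation estimated from the data. Named genes are Nr5a2, up to 8 rises and 8 falls of largest size per comparison among genes that passed, reached 5 CPM and did not overlap between groups, and up to 4 members of each list with the smallest p. Symbols that only number a predicted gene were skipped in the ranking by size. Which of the genes picked by this rule are described was decided after their values and their stability were seen, while counts of stable calls cover all genes picked. Calls of the knockout comparisons, which share no libraries but share the estimate of the spread, were compared with Fisher's exact test.

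The alternatives were DESeq2 1.42.0, RLE normalization, no filter on low counts, only the groups compared in the fit, all libraries thinned to the depth of the smallest, the replicate number as a block, each library left out in turn, and an estimated correlation for the lists. Leaving out 1 HFD knockout leaves 1 such library, which is then assumed to vary like the other groups. Thinning with the genes tested held fixed, and a count over genes without a pseudogene copy, were added after the data were seen. For the latter, GENCODE transcripts of the tested genes were aligned to annotated pseudogenes, and a copy was an alignment of at least 200 bases at 90% identity. This search covered 99.2% of tested genes and found a copy for 12.1% of those searched. Genes that could not be searched were left out of that count too.

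The procedure was tested on simulated counts with known fold changes, drawn at the real depths with 200 of the genes changed. For the knockout comparison on SD, edgeR recovered 49.3% of 2-fold and 84.8% of 4-fold changes, and 5.10% of its calls were false. On HFD it recovered 55.2% and 92.4%, with 8.87% false calls. For the difference of the knockout effect between diets it recovered 35.8% and 56.1%, with 4.69% false calls. For the diets in controls it recovered 59.7% and 89.4%, with 9.09% false calls, and in knockouts 53.7% and 80.3%, with 5.00% false calls. Each comparison was drawn once, so the false shares rest on 3 to 11 genes. Simulated changes went up to 4-fold, as often up as down. In the real diet comparisons 3622 and 3196 genes passed, and in controls 344 were at least 8-fold higher. The rates for the diets may therefore not hold for the real data.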

Results

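Liver RNA of male mice of a mixed 129SvEV-C57BL/6 background, aged 14 weeks, that carried floxed alleles of Nr5a2 was sequenced as 12 libraries. This gene encodes the nuclear receptor LRH-1, a regulator of bile acid, cholesterol and phospholipid genes. Knockout animals had received Cre recombinase by AAV8, an adeno-associated virus vector that reaches hepatocytes, and controls were floxed animals without Cre, given an eGFP vector according to the series. The libraries came from animals on a standard diet (SD, 3 control and 3 knockout libraries) or on a high-fat diet (HFD, 4 and 2) for 6 weeks. Total counts were 2371167 to 3404570 in SD libraries and 7463792 to 10875478 in HFD libraries. Genes with a count numbered 13586 to 13950 and 15137 to 15828. The ribosomal RNA gene Rn45s took 0.291% to 0.460% of counts on SD and 0.985% to 1.32% on HFD. Ribosomal protein genes took 0.137% to 0.183% and 0.683% to 0.807%. Diet and sequencing cohort therefore cannot be told apart in these libraries. The first principal component (60.0% of variance) separated the diets, and the second (11.3%) separated the genotypes within each diet. On the second, HFD control 1 (-3.34) lay between the other HFD controls (11.8 to 18.8) and the HFD knockouts (-24.4 and -20.6).

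**Figure D1:**
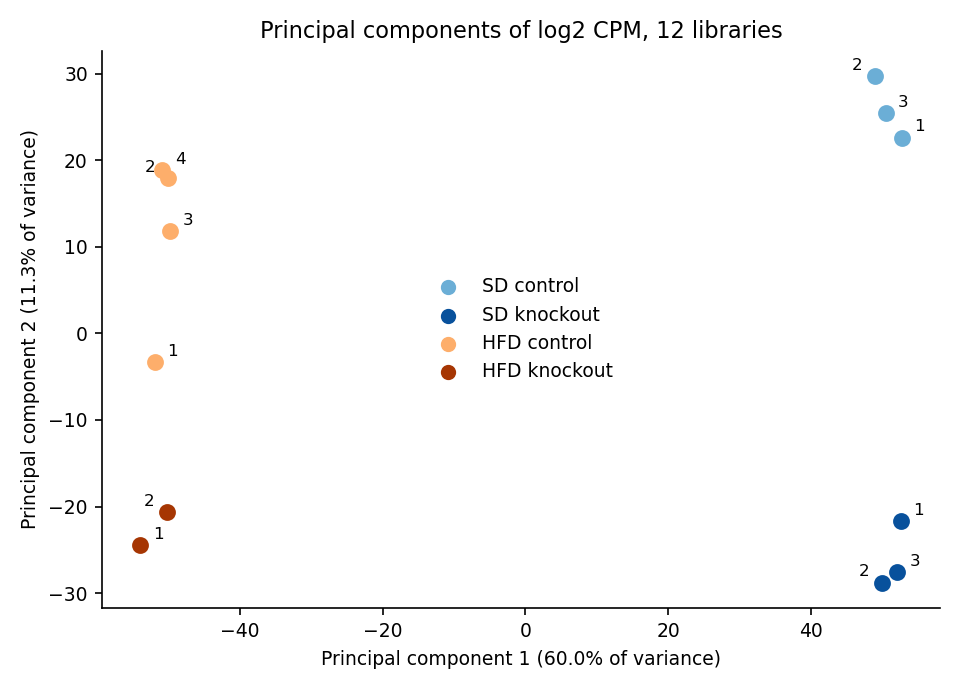
Principal components of log2 CPM of the 12 libraries, with the replicate number beside each point and the share of variance on each axis. The first component separates the diets, and on the second HFD control 1 sits at -3.34, between the other HFD controls and the HFD knockouts.

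Counts of Nr5a2 itself were not lower in the libraries labelled knockout. Nr5a2 stood at 84.4, 74.8 and 85.8 CPM in the SD controls and at 95.3, 100.1 and 94.7 CPM in the libraries labelled SD knockout (log2 fold change 0.24, SE 0.11, edgeR adjusted p = 0.288). It stood at 77.0, 74.5, 64.3 and 66.8 CPM in the HFD controls and at 69.1 and 84.5 CPM in the libraries labelled HFD knockout (0.12, SE 0.11, adjusted p = 0.719). The difference between these changes was -0.12 (adjusted p = 0.919). The sources used here do not say which exons the deletion removes, and counts summed over a gene check the deletion only where its exons are removed. The knockout groups below are therefore groups by label, and each direction rests on those labels.

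On SD, known targets of LRH-1 fell in the libraries labelled knockout. Nr0b2, which encodes the corepressor SHP, was at 12.9 ± 2.36 CPM in controls (SD, n = 3) and had no count in any knockout (n = 3), at least 35.9-fold lower (adjusted p = 0.000381). Cyp8b1, the sterol 12-hydroxylase that sets the share of cholic acid, went from 28.3 ± 16.8 to 1.97 ± 1.78 CPM (log2 fold change -3.77, SE 0.61, adjusted p = 0.00244), with -3.17 without SD control 1 and -4.88 without SD knockout 1. Both subunits of a sterol exporter, Abcg5 (-1.82, SE 0.22, adjusted p = 0.000269) and Abcg8 (-1.57, SE 0.15, adjusted p = 4.73e-05), and the HDL receptor Scarb1 (-0.89, SE 0.11, adjusted p = 0.000269) fell as well. Of the 12 listed targets, 8 fell and 0 rose over all genes tested, and 10 fell adjusted over the list alone. As a list they passed at camera adjusted p = 5.23e-22 (adjusted p = 0.00145 with an estimated correlation).

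**Figure D2:**
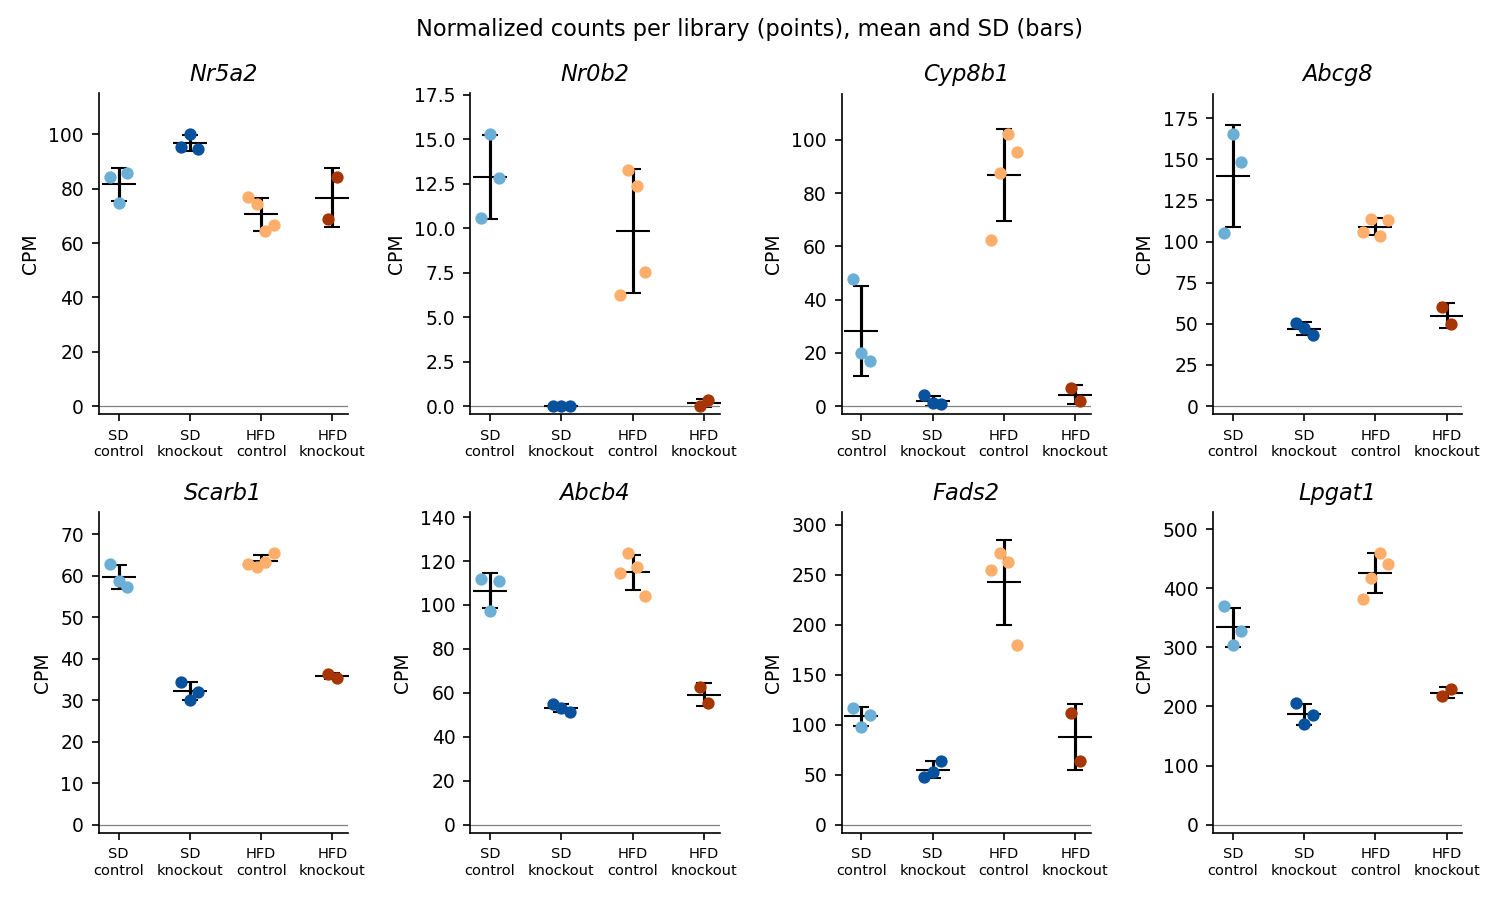
CPM of Nr5a2 and 7 other genes in each library (points), with the mean and SD of each group (bars), on linear axes. Nr5a2 lies between 64.3 and 100.1 CPM in all 12 libraries, while Nr0b2 has no count in any SD knockout.

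Over all genes, 173 were higher and 353 lower in SD knockouts, 73 and 132 of them by at least 2-fold, and 2120 had an unadjusted p under 0.05. Of all genes tested, 22.6% did not overlap between the groups, where chance gives 10%. The largest rises included the protease inhibitor gene Serpine2 (2.96, SE 0.27, adjusted p = 4.32e-05) and the transcription factor gene Olig1 (4.33, SE 0.73, adjusted p = 0.00318). Among the largest falls was Hamp2 (-5.62, SE 0.82, adjusted p = 0.0011), whose counts are uncertain because it is a close paralog of the hepcidin gene. Without SD knockout 3 it was -6.57. Acpp had 111 counts over the controls and 1 over the knockouts, in SD knockout 1, a ratio of 112 (exact 95% interval 19.6 to 4447, adjusted p = 0.00155). The ratio was 73.3 without SD knockout 3 (exact 95% interval 12.9 to 2921), and without SD knockout 1 Acpp was at least 23.3-fold lower. The total of 526 calls became 331 without SD control 2, 229 without SD control 3, 255 without SD knockout 2 and 220 without SD knockout 3. Of the 64 genes that the naming rule picked and that passed, 32 passed under every alternative and left-out library in which they were tested, and DESeq2 ended 0 of these calls.

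Bile acid and sterol transporters fell on SD, with 7 of 13 lower and 1 higher and the same counts adjusted over the list alone. The list passed at camera adjusted p = 5.95e-11 (adjusted p = 0.00308 with an estimated correlation). Abcc3, a basolateral bile acid exporter, went from 314 ± 29.6 to 56.3 ± 26.4 CPM (-2.48, SE 0.34, adjusted p = 0.000634), and Abcb4, the canalicular phosphatidylcholine flippase, from 107 ± 8.08 to 53.1 ± 1.90 CPM (2.01-fold lower, adjusted p = 0.000128). In bile acid synthesis 4 of 14 genes fell and 0 rose, among them Hsd3b7 (-0.95, SE 0.17, adjusted p = 0.00526). Adjusted over the list alone, 3 were higher and 7 lower. That list passed at camera adjusted p = 0.0164 (adjusted p = 0.336 with an estimated correlation) and no longer passed without SD control 1 or SD knockout 3 (adjusted p up to 0.186).

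Genes that make polyunsaturated fatty acids and phosphatidylcholine also fell on SD. The desaturases Fads1 (629 ± 75.3 to 301 ± 57.2 CPM, -1.07, SE 0.18, adjusted p = 0.003) and Fads2 (-0.98, SE 0.20, adjusted p = 0.0118) and the elongase Elovl5 (-1.92, SE 0.44, adjusted p = 0.0218) were the 3 of 9 that fell, with 4 lower adjusted over the list alone. That list passed at camera adjusted p = 0.00475 (adjusted p = 0.298 with an estimated correlation). In phosphatidylcholine and methyl metabolism 6 of 21 fell and 0 rose, and 7 fell adjusted over the list alone (camera adjusted p = 2.12e-05, adjusted p = 0.150 with an estimated correlation). They included Pemt, which methylates phosphatidylethanolamine (-1.08, SE 0.11, adjusted p = 7.25e-05), Gnmt, a consumer of S-adenosylmethionine (-1.27, SE 0.16, adjusted p = 0.00044), and Mat1a, which makes it (-1.22, SE 0.19, adjusted p = 0.00178). Of 15 acyl chain remodeling genes only the acyltransferase gene Lpgat1 passed (-0.84, SE 0.11, adjusted p = 0.000622), and the list did not (adjusted p = 0.0900). Fads2 lost its call without SD control 3, SD knockout 1 or SD knockout 2 (adjusted p up to 0.0556), and Elovl5 without SD control 3 or any SD knockout (adjusted p up to 0.117).

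Lists of central lipid and glucose metabolism fell on SD by camera, with few members that passed alone. In lipogenesis and triglyceride synthesis 2 of 18 fell, the acyltransferase gene Agpat2 (-1.46, SE 0.20, adjusted p = 0.000703) and the lipogenic regulator Srebf1 (-0.81, SE 0.17, adjusted p = 0.0138), and Lpin1 rose (1.46, SE 0.36, adjusted p = 0.0295). Adjusted over the list alone 1 was higher and 5 lower, and camera gave adjusted p = 0.00359 (adjusted p = 0.298 with an estimated correlation). In cholesterol synthesis and uptake 6 of 24 fell, 7 adjusted over the list alone, among them Insig1 (-0.74, SE 0.15). Camera gave adjusted p = 0.00359 for it (adjusted p = 0.523 with an estimated correlation). Fatty acid oxidation had 2 of 23 lower, also adjusted over the list alone, such as the peroxisomal thiolase gene Acaa1b (-1.19, SE 0.24, adjusted p = 0.00911), at camera adjusted p = 0.000209 (adjusted p = 0.432 with an estimated correlation). Lipoprotein genes had 5 of 17 lower, such as Apoc1 (-0.89, SE 0.12, adjusted p = 0.00056), and Apoa4 higher (1.46, SE 0.27, adjusted p = 0.00657). Adjusted over the list alone 1 was higher and 6 lower (camera adjusted p = 0.00359, adjusted p = 0.0762 with an estimated correlation). Glucose metabolism had 2 of 14 lower, such as the gluconeogenic gene Fbp1 (-0.60, SE 0.09, adjusted p = 0.00128). Adjusted over the list alone 3 fell (camera adjusted p = 0.0227, adjusted p = 0.298 with an estimated correlation).

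The lipid droplet gene Cidec rose on SD from 1.29 ± 0.869 to 11.6 ± 2.98 CPM (3.25, SE 0.82, adjusted p = 0.0354), the only 1 of 14 lipid droplet genes to pass, with 2 adjusted over the list alone. Plin4 stood at 5.52 ± 3.36 and 23.6 ± 13.7 CPM (2.12, SE 0.62, adjusted p = 0.0675), and the list did not pass (adjusted p = 0.0808, and adjusted p = 0.603 with an estimated correlation). Plin4 passed with DESeq2 (adjusted p = 0.0384), no filter on low counts (0.00263), only the groups compared (0.0122) and after thinning (0.0484). The list passed under the last 3 of these (0.0465, 0.0200 and 0.0477) and without SD control 2 (0.0162) or SD knockout 3 (0.0164). Calls in these lipid and glucose groups ended without a library for Srebf1 (SD control 3 or knockout 1, adjusted p up to 0.0838), Insig1 (SD control 3, 0.0602), Apoa4 (SD control 3, 0.0539) and Acaa1b (SD knockout 2 or 3, 0.0552). They ended likewise for Lpin1 (every SD library but control 1, 0.155, with a log2 fold change of 2.11 without control 1) and Cidec (every one, 0.175). The cholesterol list no longer passed without SD knockout 1 (adjusted p up to 0.535), and the glucose list without SD control 1 or SD knockout 2 or with only the groups compared (up to 0.169).

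Markers of both liver zones fell on SD. Of 10 pericentral hepatocyte genes 3 fell, and 4 adjusted over the list alone (camera adjusted p = 2.12e-05, adjusted p = 0.0945 with an estimated correlation). They included the ornithine aminotransferase gene Oat (793 ± 64.8 to 108 ± 17.3 CPM, -2.87, SE 0.27, adjusted p = 4.32e-05) and the transcription factor gene Tbx3 (-1.68, SE 0.20, adjusted p = 0.000329). Of 10 periportal genes 5 fell, such as Ctsc (-1.71, SE 0.24, adjusted p = 0.000934) and Gls2 (-0.93, SE 0.17, adjusted p = 0.00441). The periportal gene Cyp2f2 rose (0.85, SE 0.17, adjusted p = 0.00908), a call that ended without SD control 3 (adjusted p = 0.0647). The counts were the same adjusted over the list alone (camera adjusted p = 2.71e-05, adjusted p = 0.0762 with an estimated correlation). The stellate cell and fibroblast list was higher (camera adjusted p = 0.0227, adjusted p = 0.414 with an estimated correlation) with 0 of 10 members past the edgeR test and 1 adjusted over the list alone. Its member Col1a2 stood at 9.43 ± 3.02 and 19.3 ± 6.54 CPM (0.99, SE 0.37, adjusted p = 0.167), and the list no longer passed without SD control 1 or SD knockout 2 (adjusted p up to 0.153).

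Another 13 lists did not pass on SD. Camera adjusted p was 0.186 for xenobiotic cytochrome P450 genes, 0.202 for endoplasmic reticulum stress, acute phase and cholangiocyte genes, 0.207 for NRF2 and glutathione genes, and 0.249 for cell cycle genes. It was 0.460 for male-biased, female-biased and liver transcription factor genes, 0.559 for endothelial genes, 0.883 for interferon response genes and 0.899 for Kupffer cell and circadian clock genes. The cytochrome P450 list passed without SD knockout 1 (0.00333), and the acute phase list without SD control 1 (0.00443) or SD knockout 2 (0.0212). Among 15 cytochrome P450 genes Cyp2c55 rose (2.01, SE 0.30, adjusted p = 0.00113) and 3 fell (4 adjusted over the list alone), such as Cyp2c38 (-2.10, SE 0.42, adjusted p = 0.00911, up to 0.0540 without SD knockout 2 or 3, and a log2 fold change of -2.80 without SD knockout 1). Among 10 cell cycle genes Ccnd1, which encodes cyclin D1, rose (1.42, SE 0.37, adjusted p = 0.0415), the only 1 also adjusted over the list alone, and lost its call without any single SD library but knockout 1 (up to 0.154). Among male-biased genes Ugt2b38 (3.13, SE 0.73, adjusted p = 0.0237) and Serpina12 (2.74, SE 0.68, adjusted p = 0.0316) rose and 0 fell, with 3 higher and 1 lower adjusted over the list alone. Both lost their calls without SD control 2 or 3 or SD knockout 2 or 3, and Serpina12 also without SD control 1 (adjusted p up to 0.129 and 0.163). The median and mean log2 fold change differed in sign for the female-biased (0.76 and -0.43), male-biased (-0.05 and 0.48), interferon response (-0.03 and 0.10), circadian (-0.01 and 0.06) and transcription factor lists (-0.12 and 0.0037).

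On HFD, the libraries labelled knockout again had lower counts of LRH-1 targets. Nr0b2 went from 9.86 ± 3.48 CPM in controls (SD, n = 4) to 0.167 ± 0.237 CPM in knockouts (n = 2), 342 counts against 3, all in HFD knockout 2, a ratio of 51.9 (exact 95% interval 17.6 to 253, adjusted p = 0.000378). The ratio was 28.8 without HFD knockout 1 (exact 95% interval 9.76 to 140.2), and without HFD knockout 2 Nr0b2 was at least 23.7-fold lower. Cyp8b1 went from 86.9 ± 17.3 to 4.30 ± 3.55 CPM (-4.39, SE 0.48, adjusted p = 0.000169), with -5.58 without HFD knockout 1 and -3.66 without HFD knockout 2. Scarb1 (-0.82, SE 0.10, adjusted p = 0.000424) and Abcg8 (-0.99, SE 0.15, adjusted p = 0.00212) fell as well. Of 12 targets 7 fell and 0 rose, and 9 fell adjusted over the list alone. They passed as a list at camera adjusted p = 2.24e-18 (adjusted p = 0.00404 with an estimated correlation).

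Over all genes, 125 were higher and 200 lower in HFD knockouts, 71 and 96 by at least 2-fold, and 1687 had an unadjusted p under 0.05. Of all genes tested, 22.2% did not overlap, where chance gives 13.3%. Among the largest changes, Paqr9 went from 310 ± 54.7 to 28.2 ± 0.593 CPM (-3.46, SE 0.21, adjusted p = 6.58e-07). The oxysterol-binding protein gene Osbpl3 fell (-3.29, SE 0.48, adjusted p = 0.00145), Acpp fell (-4.80, SE 0.66, adjusted p = 0.000977), and Corin rose (3.81, SE 0.55, adjusted p = 0.00133). Acpp was at -5.87 without HFD knockout 1 and -4.07 without HFD knockout 2, and Corin at 5.43 without HFD control 1. On HFD some shares of counts did not overlap between the groups. The nuclear RNA Malat1 took 1.13% to 1.37% of counts in HFD controls and 1.58% to 1.79% in HFD knockouts, albumin 7.58% to 8.45% and 10.02% to 13.7%, and the top 10 genes 18.4% to 20.5% and 22.6% to 24.9%. On SD these ranges overlapped for Malat1 (0.461% to 0.689% and 0.677% to 1.07%), albumin (8.82% to 11.1% and 8.98% to 13.2%) and the top 10 genes (20.4% to 22.5% and 20.3% to 23.97%). The total of 325 calls became 602 without HFD control 1, 191 without HFD control 2, 209 without HFD control 4, 85 without HFD knockout 1 and 203 without HFD knockout 2. It was 127 with only the groups compared and 518 with no filter on low counts. Of the 53 genes that the naming rule picked and that passed, 24 passed under every alternative and left-out library in which they were tested, and DESeq2 ended 6 of these calls.

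Transporters fell on HFD, 7 of 13 lower and 1 higher, with 8 and 2 adjusted over the list alone. Their camera adjusted p was 1.40e-08 (adjusted p = 0.00856 with an estimated correlation). Slc10a1, the sodium-dependent bile acid importer, went from 733 ± 209 to 162 ± 4.85 CPM (-2.17, SE 0.23, adjusted p = 0.000133), and Abcb4 fell (-0.96, SE 0.11, adjusted p = 0.000234). Bile acid synthesis had 2 of 14 lower, also adjusted over the list alone (camera adjusted p = 0.00692, adjusted p = 0.219 with an estimated correlation). Polyunsaturated fatty acid synthesis had 2 of 9 lower, Fads2 (243 ± 42.5 to 87.8 ± 33.4 CPM, -1.47, SE 0.21, adjusted p = 0.00125) and Fads1 (-0.91, SE 0.19, adjusted p = 0.0181). Of the 9, 1 was higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000338, adjusted p = 0.189 with an estimated correlation). Phosphatidylcholine and methyl metabolism had 4 of 21 lower, 7 adjusted over the list alone (camera adjusted p = 0.000338, adjusted p = 0.189 with an estimated correlation). Among them were Gnmt (-1.48, SE 0.18, adjusted p = 0.000314), Pemt (-0.54, SE 0.11, adjusted p = 0.0126) and Pcyt1a, the rate-limiting gene of the choline branch (-0.55, SE 0.11, adjusted p = 0.0126). Lpgat1 fell (-0.93, SE 0.12, adjusted p = 0.000708) in an acyl chain remodeling list that did not pass (adjusted p = 0.359, median 0.08, mean -0.08). Of its 15 genes 1 was higher and 4 lower adjusted over the list alone. Without HFD knockout 1 the acyl chain remodeling list passed (0.0335). Calls ended without HFD knockout 1 or 2 for Pemt (adjusted p up to 0.111, and 0.0948 after thinning) and Pcyt1a (up to 0.0960). The call of Fads1 ended without HFD control 2 or HFD knockout 2 (up to 0.187), and all 3 also with only the groups compared. Without HFD knockout 2 the polyunsaturated list no longer passed (adjusted p up to 0.0943).

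Lipid droplet genes rose on HFD. Cidec went from 3.26 ± 2.85 to 29.2 ± 19.2 CPM (3.07, SE 0.47, adjusted p = 0.00208) and Plin4 from 11.7 ± 8.38 to 50.2 ± 12.5 CPM (2.07, SE 0.43, adjusted p = 0.0164). The monoacylglycerol acyltransferase gene Mogat1 went from 0.905 ± 0.454 to 3.81 ± 2.08 CPM (2.01, SE 0.50, adjusted p = 0.0447). These were 3 of 14, with 4 adjusted over the list alone (camera adjusted p = 0.000387, adjusted p = 0.189 with an estimated correlation). Of 7 adipocyte markers 3 reached the test and Cfd, a complement factor gene, alone passed, in a list too small for camera. The 7 summed to 69.3 ± 28.4 CPM in HFD knockouts and 14.0 ± 2.87 CPM in HFD controls. On SD the sums were 15.3 ± 7.70 and 8.80 ± 2.66 CPM. Most of the sum in HFD knockouts was Cfd, at 52.9 ± 22.8 and 1.11 ± 1.32 CPM on HFD (42.2-fold higher, adjusted p = 0.000204). Without HFD control 1 the log2 fold change of Cfd was 6.81, where it is 5.40 with all libraries, that of Cidec 3.97 and that of Plin4 2.75. Without HFD knockout 1 that of Cidec was 2.19. Calls ended for Cidec without HFD knockout 1 (adjusted p up to 0.0993), and for Plin4 without HFD control 2 or 4 or HFD knockout 1 and with DESeq2 or only the groups compared (up to 0.214). The call of Mogat1 ended with DESeq2 or only the groups compared (up to 0.114). Its counts were too low for the test after thinning and without any single HFD library but knockout 2 (0.0413). The list no longer passed without HFD knockout 1 (up to 0.0557).

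Other metabolic lists fell on HFD. Lipogenesis and triglyceride synthesis had 2 of 18 lower, also adjusted over the list alone, Agpat2 (-1.48, SE 0.18, adjusted p = 0.00039) and the pyruvate kinase gene Pklr (-0.92, SE 0.18, adjusted p = 0.0135), at camera adjusted p = 0.00224 (adjusted p = 0.189 with an estimated correlation). Cholesterol synthesis had 2 of 24 lower, such as Hsd17b7 (-0.71, SE 0.15, adjusted p = 0.0163). Adjusted over the list alone 5 fell (camera adjusted p = 0.00168, adjusted p = 0.372 with an estimated correlation). Lipoproteins had 3 of 17 lower, such as Apom (-1.24, SE 0.28, adjusted p = 0.0281), 6 adjusted over the list alone (camera adjusted p = 2.90e-05, adjusted p = 0.0146 with an estimated correlation). Glucose metabolism had 2 of 14 lower, Pklr and the gluconeogenic gene Pck1 (-1.02, SE 0.21, adjusted p = 0.0139), 3 adjusted over the list alone (camera adjusted p = 0.00715, adjusted p = 0.189 with an estimated correlation). Calls ended without HFD knockout 1 or 2 for Pklr (adjusted p up to 0.110), Pck1 (0.113) and Hsd17b7 (0.258). The call of Apom ended without any single HFD library but control 1 (0.218). With only the groups compared, Apom lost its call as well. The cholesterol list no longer passed without HFD knockout 2 (adjusted p up to 0.866), nor the glucose list (0.209), nor lipogenesis, which HFD control 1 also decided (0.410).

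Male-biased liver genes fell on HFD, 4 of 12 lower and 0 higher, with 5 and 1 adjusted over the list alone. Their camera adjusted p was 0.000338 (adjusted p = 0.189 with an estimated correlation). They included the hydroxysteroid dehydrogenase gene Hsd3b5 (110 ± 83.5 to 15.9 ± 10.2 CPM, -2.76, SE 0.64, adjusted p = 0.0295), Cyp4a12b (-2.71, SE 0.60, adjusted p = 0.0216) and the organic anion transporter gene Slco1a1 (-0.98, SE 0.19, adjusted p = 0.0124). The female-biased list did not pass (adjusted p = 0.331, and 0.0360 without HFD knockout 2). Its member Atp6v0d2 fell on HFD (-3.16, edgeR adjusted p = 0.00212) and on SD (-5.77, adjusted p = 0.00256). Another member, Cyp2a4, stood at 35.6 CPM in HFD knockout 1 and 1.00 CPM in HFD knockout 2 against 1.48 ± 1.43 CPM in controls (3.50, SE 0.86, adjusted p = 0.0404). Without HFD knockout 1 the log2 fold change of Cyp2a4 was -0.61 and its adjusted p 0.946. The call also ended without HFD control 2, 3 or 4 (adjusted p up to 0.119), with DESeq2 (0.166) and with only the groups compared (0.160). The log2 fold change was 4.50 without HFD control 1 and 4.48 without HFD knockout 2. NRF2 and glutathione genes were higher, 2 of 11, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0139, adjusted p = 0.302 with an estimated correlation). These were the glutathione transferase paralogs Gsta1 (3.18, SE 0.60, adjusted p = 0.0093) and Gsta2 (1.87, SE 0.38, adjusted p = 0.0138). Cyp2c55 rose (3.43, SE 0.29, adjusted p = 1.54e-05) among 15 cytochrome P450 genes, of which 1 fell, with 5 higher and 3 lower adjusted over the list alone. As a list they did not pass (adjusted p = 0.0765, median -0.11, mean 0.50), but they did without HFD control 2 (0.0163), HFD control 4 (0.0396) or HFD knockout 2 (0.0160). Without HFD knockout 1 the calls of Slco1a1 (adjusted p up to 0.228), Gsta1 (0.306), and Gsta2 (0.269) ended, as did those of Cyp4a12b (0.264, also without HFD knockout 2) and Hsd3b5 (0.328, also without HFD control 4 or HFD knockout 2). With only the groups compared, Slco1a1, Gsta1, Cyp4a12b and Hsd3b5 also lost their calls (adjusted p up to 0.136). That of Cyp4a12b ended after thinning too (0.0559), where Gsta1 was too low for the test. Fold changes also moved for Hsd3b5 (-2.12 without HFD control 3, -3.66 without HFD knockout 2), Cyp4a12b (-1.96 without HFD control 3) and Cyp2c55 (2.74 without HFD knockout 1). That of Gsta1 was 3.92 without HFD control 1, 2.06 without HFD knockout 1 and 3.84 without HFD knockout 2. The male-biased and NRF2 lists no longer passed without HFD knockout 1 (both up to 0.172), nor the NRF2 list after thinning (0.0934).

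Of 10 pericentral genes 4 fell on HFD, also adjusted over the list alone (camera adjusted p = 4.85e-05, adjusted p = 0.147 with an estimated correlation). Oat (-2.48, SE 0.30, adjusted p = 0.000314) and Tbx3 (-1.40, SE 0.20, adjusted p = 0.00126) fell, and Rhbg, an ammonium transporter gene, went from 2.77 ± 1.13 CPM to no count in either knockout, at least 14.9-fold lower (adjusted p = 0.00224), and was too low for the test after thinning or without HFD control 1. The periportal list did not pass (adjusted p = 0.109, and 0.0438 with only the groups compared), with 2 of 10 lower (4 adjusted over the list alone) and Cyp2f2 higher (1.05, SE 0.17, adjusted p = 0.0031). Interferon response genes were higher as a list, with 1 of 17 higher, also adjusted over the list alone (camera adjusted p = 0.000338, adjusted p = 0.219 with an estimated correlation). Cell cycle genes were higher as a list with 0 of 10 past the edgeR test and 3 higher adjusted over the list alone (camera adjusted p = 0.000648, adjusted p = 0.189 with an estimated correlation). Ccnd1 stood at 32.7 ± 15.1 and 76.3 ± 12.2 CPM (1.21, SE 0.32, adjusted p = 0.0582), and passed with no filter on low counts (0.00141) and without HFD control 1 (0.00944) or HFD control 4 (0.0469). Markers of other cell types were higher as lists with 0 members past the edgeR test. Camera adjusted p was 0.0122 for stellate cells and fibroblasts (adjusted p = 0.273 with an estimated correlation) and 0.0164 for endothelial cells (adjusted p = 0.154 with an estimated correlation). It was 0.0247 for cholangiocytes (adjusted p = 0.184 with an estimated correlation), with 2 of 5 higher adjusted over the list alone. The liver transcription factor list was lower (adjusted p = 0.0247, and adjusted p = 0.189 with an estimated correlation) with 0 of 13 past the edgeR test and 1 lower adjusted over the list alone. The stellate and cholangiocyte lists no longer passed without HFD knockout 1 (adjusted p up to 0.172 and 0.198), and the endothelial list without HFD knockout 2 (0.140). The transcription factor list no longer passed without HFD control 3 or 4 or either HFD knockout or after thinning (up to 0.0934), nor the cholangiocyte list with no filter on low counts (0.0968).

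The other lists did not pass on HFD, with camera adjusted p of 0.0749 for acute phase, 0.0990 for Kupffer cell, 0.359 for fatty acid oxidation, 0.531 for circadian clock and 0.719 for endoplasmic reticulum stress genes. The acute phase list passed without HFD control 2 (0.000661) or HFD knockout 2 (0.0158), with no filter on low counts (0.0375) and with only the groups compared (0.0471). Without HFD control 1 the Kupffer cell list passed (0.00540), and without HFD knockout 1 fatty acid oxidation did (0.00199). Endoplasmic reticulum stress genes passed as higher without HFD knockout 1 (0.0123) and as lower without HFD knockout 2 (0.0397). Lists of cell types too rare to test had summed CPM of 46.9 ± 2.90 in HFD knockouts and 30.6 ± 15.5 in HFD controls for lymphocytes, 12.8 ± 1.79 and 11.9 ± 1.94 for neutrophils, and 51.0 ± 12.2 and 39.9 ± 9.65 for red blood cells. Those of exocrine pancreas were 0.264 ± 0.216 and 0.200 ± 0.119. On SD the sums in knockouts and controls were 25.7 ± 2.56 and 25.0 ± 4.09 for lymphocytes, 4.08 ± 2.44 and 2.75 ± 1.55 for neutrophils, and 28.7 ± 2.13 and 29.2 ± 4.84 for red blood cells. For exocrine pancreas they were 0.338 ± 0.333 and 0.232 ± 0.205.

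**Figure D3:**
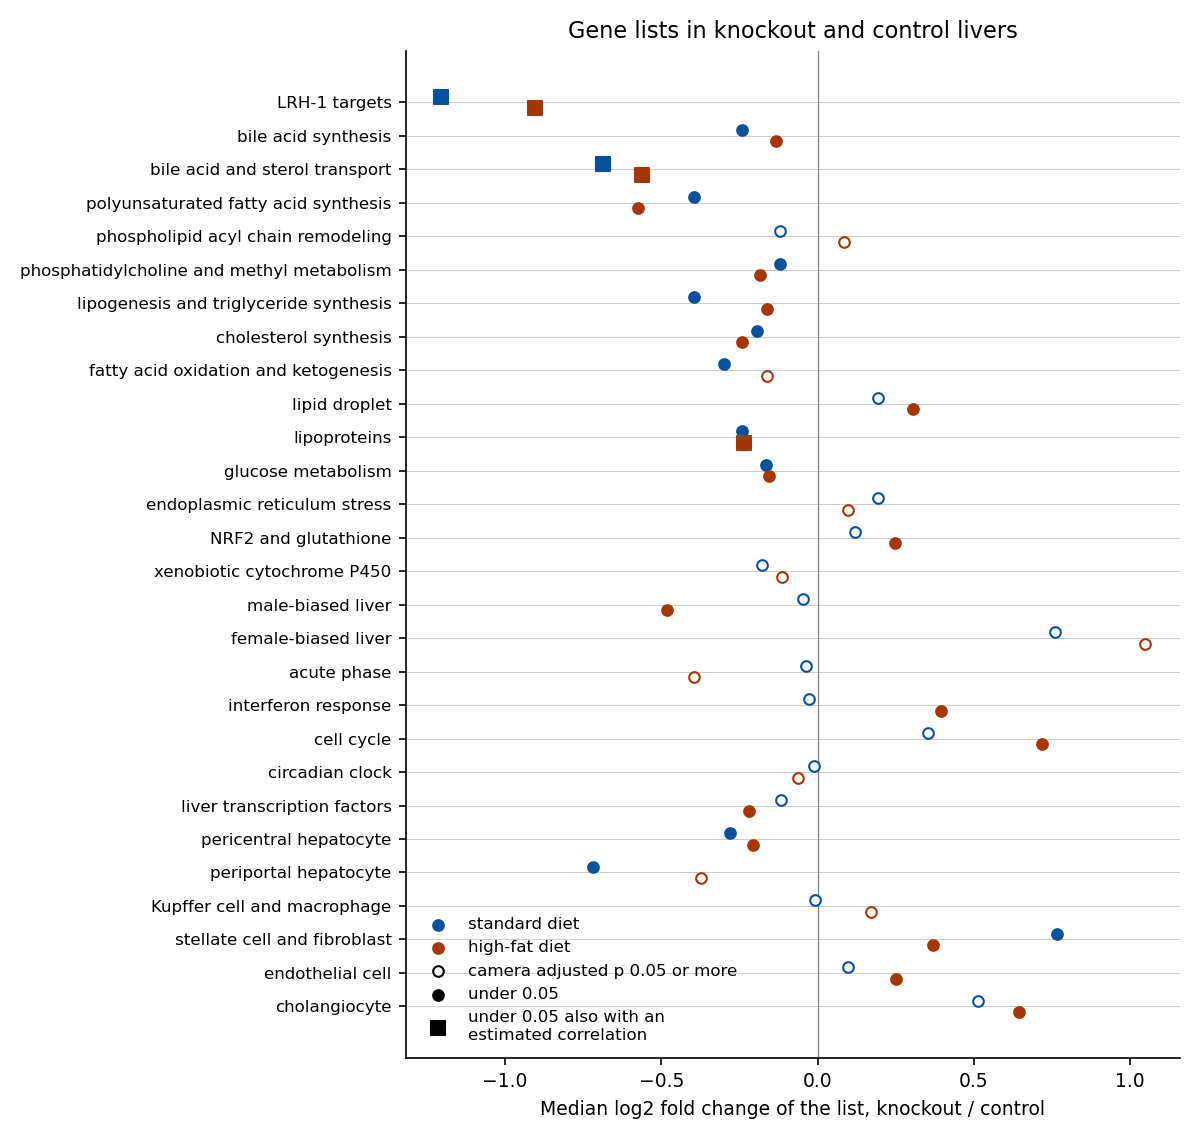
Median log2 fold change of each gene list, knockout over control, on SD and HFD. Filled symbols mark lists with a camera adjusted p under 0.05, and squares those that also pass with an estimated correlation: LRH-1 targets and transporters on both diets and lipoproteins on HFD.

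Changes in the libraries labelled knockout were shared between the diets. Of the genes higher on SD, 35 were also higher on HFD, where independent lists would share 1.80 (Fisher's exact p = 4.03e-36), and 128 were lower on both, where 5.88 would be shared (exact p = 4.47e-153). They include Nr0b2, Cyp8b1, Oat and Acpp among the falls and Cidec and Cyp2c55 among the rises. Both comparisons used the same estimate of each gene's spread, and genes are not independent units, so these exact p-values are descriptive only. No gene passed in opposite directions on the diets (0 of 688 that passed on either). Of the SD rises and falls, 84.4% and 94.9% had the same sign on HFD. Across the 688 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.77 (0.39, with Spearman's rho 0.32, across all genes). The 163 shared calls became 61 without HFD knockout 1 and 89 without HFD knockout 2, 86 with only the groups compared and 257 with no filter on low counts.

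**Figure D4:**
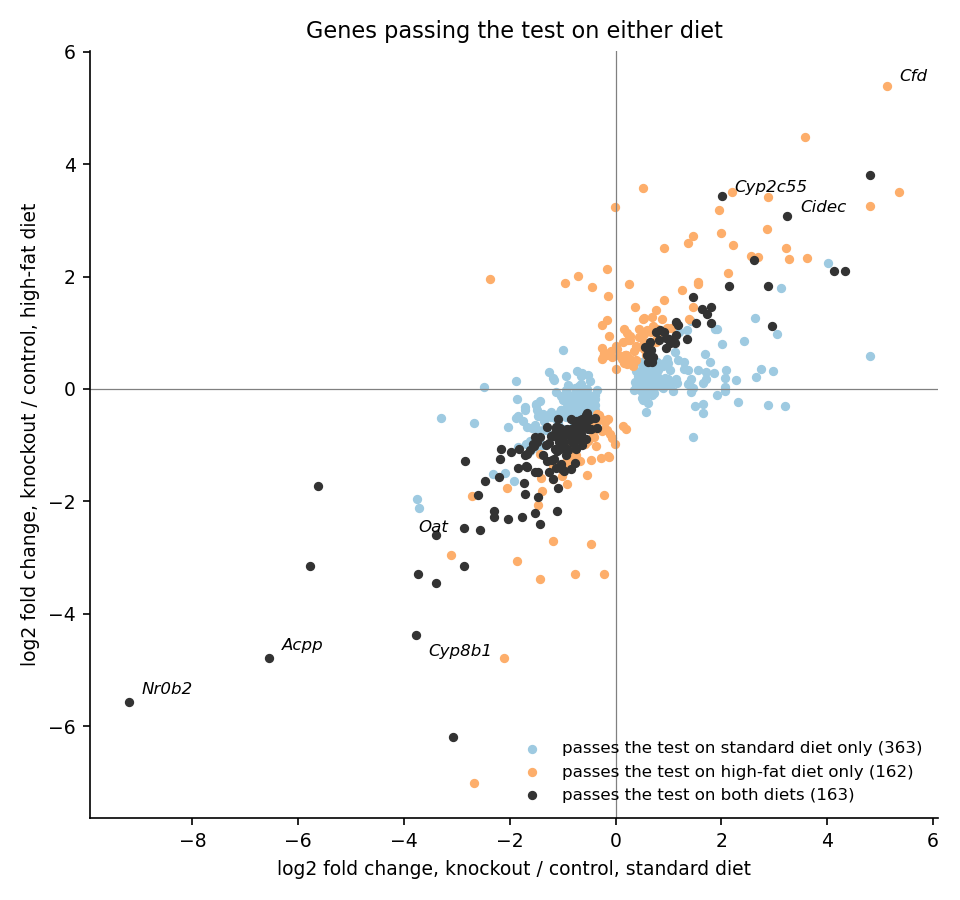
Fitted log2 fold change, knockout over control, on SD (horizontal) and HFD (vertical) for genes that passed the test on either diet. Genes that passed on both lie in the lower left (128) or upper right (35), and the position of genes with a group at 0, such as Nr0b2, depends on the prior count of the fit.

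By edgeR no single gene passed a test of whether its knockout effect differed between the diets. The count was 0, with 911 at an unadjusted p under 0.05 and a smallest adjusted p of 0.202, and DESeq2 called 30. It was 17 with no filter on low counts, 4 without SD control 1, and 1 without SD knockout 1 or HFD control 1. Apoa4 had the difference -2.32 (SE 0.38, adjusted p = 0.202), Hsd17b7 -0.91 (SE 0.21, adjusted p = 0.329), Acaa1b 1.38 (SE 0.33, adjusted p = 0.329) and Ctsc 1.39 (SE 0.33, adjusted p = 0.329). With DESeq2 these 4 passed (adjusted p of 7.00e-06, 0.0255, 0.0255 and 0.0315). In the simulated counts 12.5% of DESeq2 calls for this difference were false, against 4.69% of edgeR calls. With no filter on low counts Apoa4 (6.06e-05), Acaa1b (0.0157) and Ctsc (0.0185) passed, and Ctsc also without SD control 1 (0.0221). As lists, male-biased genes had a lower effect on HFD (camera adjusted p = 2.78e-05, adjusted p = 0.758 with an estimated correlation), with Hsd3b5 at -2.29 (SE 0.79, adjusted p = 0.544) and Slco1a1 at -0.98 (SE 0.26, adjusted p = 0.374). Cytochrome P450 genes (0.00717), and fatty acid oxidation, interferon response and periportal genes (0.00956 each) had a higher one, each lost with an estimated correlation (adjusted p = 0.758 for periportal and 0.859 for the other 3). Without HFD knockout 1 the adjusted p of the male-biased list was 0.0298. Calls ended for fatty acid oxidation without SD knockout 3 (0.206) or HFD knockout 1 (0.679), for cytochrome P450 genes without SD knockout 3 (0.112), for interferon response without SD knockout 1 (0.0791) and for periportal genes without HFD control 4 (0.0583).

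Between the diets, single genes of sterol and fatty acid synthesis were higher in HFD controls (n = 4) than in SD controls (n = 3), in a comparison that cannot be told apart from the sequencing cohort. Against all other genes their lists did not pass, with camera adjusted p of 0.111 for cholesterol, 0.216 for polyunsaturated fatty acid and 0.404 for lipogenesis genes. The sterol synthesis genes Idi1 (5.75, SE 0.37, adjusted p = 6.95e-09) and Fdps (3.31, SE 0.32, adjusted p = 1.11e-06) rose among 10 higher and 1 lower of 24. Tecr (1.49, SE 0.11), Elovl5 (1.73, SE 0.40) and Fads2 (1.16, SE 0.18) rose among 6 higher and 1 lower of 9 polyunsaturated fatty acid genes. The lipogenic genes Acaca (1.58, SE 0.21) and Mlxipl (0.84, SE 0.11) were among 6 of 18 higher, with 0 lower. The lipid droplet coat gene Plin2 (128 ± 34.7 to 293 ± 70.8 CPM, 1.19, SE 0.20, adjusted p = 0.000356) and the lipase gene Pnpla2 (0.93, SE 0.13) were among 6 of 14 higher. Bhmt (2.76, SE 0.36) and Ahcy (2.21, SE 0.12) of methyl metabolism rose. So did Apoa4 (5.66-fold, SE of log2 0.26, adjusted p = 2.48e-06), Cyp8b1 (1.63, SE 0.35, adjusted p = 0.00217) and the clock gene Per1 (0.98, SE 0.15). Cyp3a11, a xenobiotic-metabolizing enzyme gene, fell to 525 ± 240 CPM (-2.92, SE 0.37, adjusted p = 2.42e-05). The male-biased genes Cyp4a12a (-1.47, SE 0.25) and Hsd3b5 (-1.62, SE 0.47, adjusted p = 0.0161) were among 5 of 12 lower. Without SD control 1 Bhmt was at 3.62 and Cyp8b1 at 2.24, and without HFD control 3 Hsd3b5 was at -2.26. Of the genes named here, Idi1, Fdps, Tecr, Acaca, Plin2, Bhmt, Ahcy, Cyp3a11 and Hsd3b5 have pseudogene copies in the reference, which makes their folds between the cohorts uncertain. Nr5a2 differed by -0.21 (SE 0.10, adjusted p = 0.150).

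In total 1983 genes were higher and 1639 lower in HFD controls, 1070 and 168 by at least 2-fold, with 4884 at an unadjusted p under 0.05. Of all genes tested, 37.2% did not overlap, where chance gives 5.71%. By camera against all other genes, 0 of the 28 lists passed (smallest adjusted p = 0.111, for cholesterol synthesis, and adjusted p = 0.967 for every list with an estimated correlation). Among the largest rises, the zinc finger gene Zfp488 had no count in any SD control and 127 ± 6.21 CPM on HFD, at least 353-fold higher. The olfactory and vomeronasal receptor genes Olfr613 and Vmn1r58 were at least 145-fold and 124-fold higher. Genes with a pseudogene copy in the reference were frequent among the rises. Among genes searched and found without a copy, 1314 were higher and 1527 lower.

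**Figure D5:**
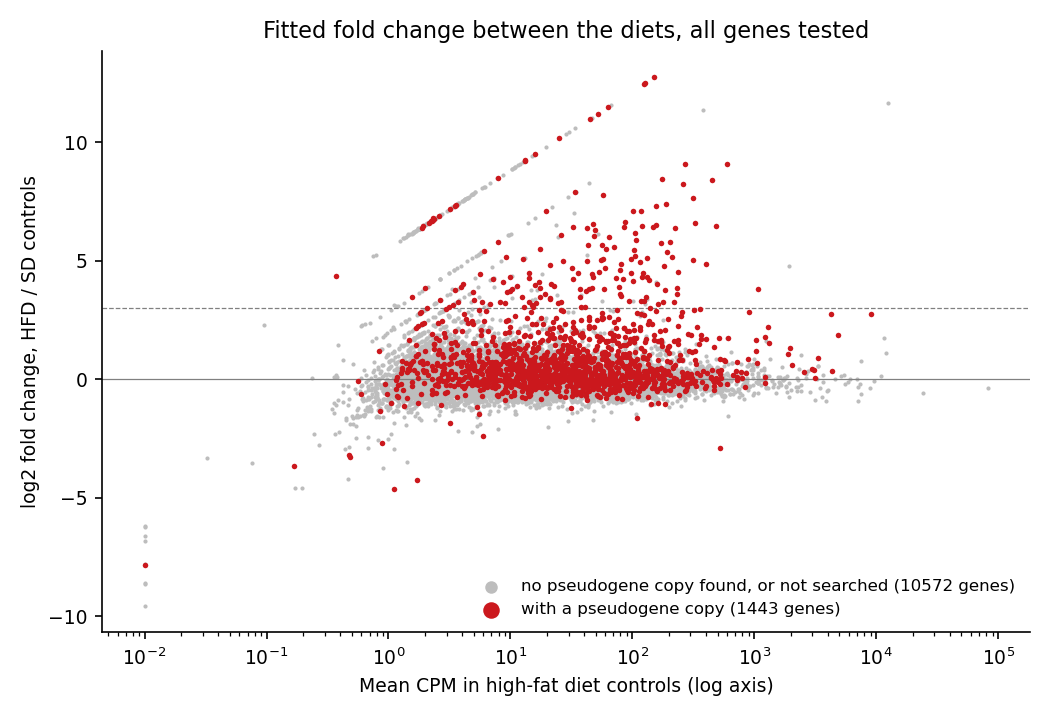
Fitted log2 fold change between HFD and SD controls against mean CPM in HFD controls (log axis) for all 12015 genes tested, with the 1443 that have a pseudogene copy in red and a dashed line at 8-fold. The slanted line of points holds genes with no count in SD controls, whose fitted values depend on the prior count, and genes at 0 in HFD controls are drawn at the left edge.

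In the libraries labelled knockout, male-biased genes were lower on HFD (n = 2) than on SD (n = 3), 7 of 12 lower and 0 higher. This was the only list past camera (adjusted p = 0.00377, adjusted p = 0.882 with an estimated correlation). They included Hsd3b5 (243 ± 93.5 to 15.9 ± 10.2 CPM, -3.92, SE 0.69, adjusted p = 0.000625), Cyp7b1 (-2.67, SE 0.48, adjusted p = 0.000758), Cyp4a12b (-3.25, SE 0.63, adjusted p = 0.00132) and Slco1a1 (-1.84, SE 0.21, adjusted p = 8.98e-06). The female-biased cytochrome P450 genes Cyp2b9 (4.69, SE 1.08, adjusted p = 0.00452) and Cyp2b13 (5.73, SE 1.30, adjusted p = 0.00411), which are paralogs, rose. Without SD knockout 1 these were 6.45 and 5.14, and without HFD knockout 2 Cyp7b1 was at -3.45 and Hsd3b5 at -4.81. Plin2 (1.70, SE 0.23, adjusted p = 5.78e-05) and the fatty acid transporter gene Cd36 (1.40, SE 0.32, adjusted p = 0.00481) were among 7 of 14 lipid droplet genes higher, with 0 lower. Acaca (1.98, SE 0.24, adjusted p = 2.1e-05) and Idi1 (5.62, SE 0.37, adjusted p = 1.1e-08) rose. Of these, Hsd3b5, Cyp2b9, Cyp2b13, Plin2, Acaca and Idi1 have pseudogene copies. In total 1792 genes were higher and 1404 lower, 1071 and 260 by at least 2-fold, with 4573 at an unadjusted p under 0.05. Among genes searched and found without a copy the majority turned, with 1181 higher and 1291 lower. Of all genes tested, 52.7% did not overlap, where chance gives 20%. Without HFD knockout 1 there were 1978 calls, Cd36 lost its call (adjusted p up to 0.0944), and 0 lists passed.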

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

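The tests of exchanged labels, of exons outside the deleted part and of thinning with the genes tested held fixed were chosen after the result was seen, as was the extension of the pseudogene search below. The estimated correlation was chosen before any result, but its use as a test of the male-biased pattern came after its result was seen.

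HFD control 1 stood apart for single genes, and on the second principal component it lay between the other HFD controls and the HFD knockouts. By the ratio of the gap to the range among the 4 HFD controls, this library lay beyond Dixon's 95% critical value for 6 of the 78 genes examined. For independent genes chance gives about 3.90 over all 4 libraries and 0.975 in a given one, and 0 genes lay outside in the others. The genes examined are those described here, many of them picked for a knockout effect, and they may vary together. These chance figures are therefore only a rough guide. The 6 genes were Cidec (ratio 0.963, 7.53 CPM against 1.74 to 1.95), Plin4 (0.936, 24.2 against 7.10 to 8.19), Cfd (0.899, 3.09 against 0.343 to 0.621), Serpine2 (0.874, 19.1 against 9.04 to 10.3), Corin (0.870, 1.81 against 0.124 to 0.343) and Rhbg (0.835, 4.45 against 1.95 to 2.36). Of these, Cidec, Plin4, Cfd, Serpine2 and Corin were also higher in HFD knockouts than in HFD controls, while Rhbg was lower there. The effects of 5 lists differed between the diets by camera: male-biased genes (adjusted p = 2.78e-05), cytochrome P450 genes (0.00717), and fatty acid oxidation, interferon response and periportal genes (0.00956 each). With an estimated correlation 0 of these calls held (adjusted p of 0.758 to 0.859). Without 1 library the 4 other than male-biased genes also lost theirs: fatty acid oxidation without HFD knockout 1 (0.679) or SD knockout 3 (0.206), cytochrome P450 genes without SD knockout 3 (0.112), interferon response without SD knockout 1 (0.0791) and periportal genes without HFD control 4 (0.0583).

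Nr5a2 counts were not lower in the libraries labelled knockout. Exchanged labels would raise LRH-1 targets in those libraries, but at least 7 of 12 passed as lower on each diet. Recombination in a minority of hepatocytes would keep losses small, but at least 28 genes passed as more than 4-fold lower on each diet. That reads come from exons outside the deleted part stays open as a candidate explanation, since the smallest adjusted p for Nr5a2 was 0.288 and the deleted exons are not given in the sources used here. No test of the protein or of single exons was possible with counts summed per gene.

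Of the genes that passed between the diets in controls, 344 were at least 8-fold higher on HFD and 20 at least 8-fold lower. Of the 336 that could be searched, 48.5% had a pseudogene copy, against 7.74% of matched uncalled genes, a ratio of 6.27 (Fisher's exact p = 6.03e-34). A first search, of protein-coding genes alone, covered too few of them and was extended to all annotated genes. This is in line with reads shared between copies being kept in one cohort and lost in the other, and it may account for part of the pattern. Lower depth on SD is argued against, since after thinning 98.8% of these genes still passed with the genes tested held fixed (73.8% where the filter on low counts was applied anew, with 254 of 254 tested). The diet itself stays open, since diet and cohort cannot be told apart. In knockouts 83.7% of these genes were also at least 8-fold higher. Knockouts differ by diet and cohort together, as controls do, so this share cannot decide between them. Of the 35 splits of the 7 controls, only the real 1 gave as many genes (3622, highest other 0). Every other split mixed the diets within a group, which adds the difference between the cohorts to the spread. These splits therefore cannot decide whether chance plays a part in that count.

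Male-biased genes had a lower knockout effect on HFD than on SD. Depth is argued against, since after thinning the adjusted p for the difference was 1.76e-05. A single library stays open: without HFD knockout 1 that p moved from 2.78e-05 to 0.0298, still under 0.05, but the fall of the list on HFD itself no longer passed (0.172). HFD control 3 had the most Hsd3b5 (225 CPM against 27.7 to 106 in other HFD controls), Cyp7b1 (245 against 94.2 to 122), Cyp4a12b (106 against 18.2 to 34.7) and Cyp4a12a (166 against 75.1 to 103). None lay beyond Dixon's critical value, and for Slco1a1, Serpina12 and Ugt2b38 the most distant library was HFD control 1. Without HFD control 3 the camera adjusted p for the difference was 0.00063. That male-biased genes vary together between livers may account for the call, since with an estimated correlation the adjusted p was 0.758. A biological difference of the knockout effect between diets stays open and cannot be told apart from the cohort.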

How the results depend on the processing

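The count over genes without a pseudogene copy and the thinning with the genes tested held fixed were chosen after the data were seen, and the other alternatives before. With RLE normalization all counts of genes and of lists stayed within 1.5 times the reported one. With DESeq2 only the difference between diets moved, to 30. With no filter on low counts HFD gave 518 calls, the difference 17 and both diets 257, and 5 lists passed for diet in controls and 7 in knockouts. With only the groups compared HFD gave 127 calls and both diets 86, and 1 and 2 lists passed for the diets. Thinned to the smallest library, 2 lists passed for diet in knockouts, and calls were 540 on SD and 226 on HFD. With an estimated correlation 2 lists passed on SD, 3 on HFD, 0 for diet in knockouts and 0 for the difference. Among genes searched and found without a copy, calls were 477 on SD, 300 on HFD and 152 on both diets.

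With 1 library left out, calls ranged from 220 to 498 on SD, 85 to 602 on HFD, 2831 to 3304 between diets in controls, 1978 to 2733 in knockouts, 0 to 4 for the difference and 61 to 217 on both diets. Lists ranged from 11 to 14, 16 to 20, 0 to 0, 0 to 5 and 4 to 8 in the same order of comparisons. The log2 fold change of Cyp2a4 on HFD ranged from -0.61 to 4.50. The endoplasmic reticulum stress list on HFD ranged in adjusted p from 0.0123 (higher, without HFD knockout 1) to 0.994 and was lower without HFD knockout 2 (0.0397). The cause was not tested, and fewer samples lower the power of each such test. The 6 SD libraries have 10 splits, too few for a share under 0.05 (real 526 calls, highest other 0, 1 as large). Of results for the genes described here with 1 library left out, 676 kept their side of the threshold, 74 lost it, 3 gained it and 1 reversed. For lists these were 615, 27, 21 and 1. The tally for genes is not a measure of stability over all picks, because the genes described were chosen after their stability was seen. Of the 64 genes that the naming rule picked and that passed on SD, 32 kept their call without any single SD library.

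Groups share replicate numbers, but same-numbered libraries did not deviate together (correlations of -0.04 to 0.12), so the numbers were not taken as pairs. The replicate block gave 595 calls on SD, 227 on HFD, 3347 and 2927 for the diets, 1 for the difference and 156 on both diets, and 2, 2 and 3 lists for the diets and the difference. Of calls for the genes described, Pemt, Pcyt1a, Mogat1 and Cyp2a4 on HFD did not pass with the block and Plin4 on SD did. Of lists, stellate (adjusted p = 0.0996) and cholangiocyte genes (0.0816) on HFD and interferon response (0.0880) and periportal genes (0.0542) for the difference did not pass with it, and lipid droplet on SD (0.0145) and Kupffer cell genes on HFD (0.0477) did. In simulated data at the real depths, 5.97% of 1.5-fold changes were found on SD, 22.4% on HFD and 0% for the difference between diets. Depth was not varied alone there.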

Other observations

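Both tests of a zonal shift were chosen after the result was seen.

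The fall of pericentral genes in the libraries labelled knockout could reflect a shift from pericentral to periportal expression. On SD such a shift would raise the periportal list, but its median log2 fold change was -0.72, which argues against it for the list as a whole. Its member Cyp2f2 rose, however, and Gls2 is also a listed LRH-1 target. With an estimated correlation the list did not pass (camera adjusted p = 0.0762), so a shift in part of these genes cannot be excluded. On HFD the periportal median was -0.37 and the list did not pass, so the shift stays open there.

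Gapdh, often used as a loading reference and chosen here after its values were seen, stood at 1.17 ± 1.10 CPM in SD controls (n = 3) and 598 ± 78.4 CPM in HFD controls (n = 4), with 1.66 ± 0.679 and 523 ± 42.5 CPM in the knockouts. Its transcript aligned to 159 annotated pseudogene copies.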
